A study of Rattus norvegicus with 17 samples.

How the data were processed

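Gubernacula, the fetal ligaments that anchor the testis near the abdominal wall, were dissected from male Long Evans rat fetuses on gestational day 17. Per the labels' protocols, 2 gubernaculum bulbs per biological replicate were cultured on filter inserts at an air and liquid interface for 24 h in control medium. They were then cultured for a further 24 h without hormone or with insulin-like 3 (Insl3), a peptide hormone of fetal Leydig cells, at 10 or 100 nM. Total RNA was extracted, biotin-labelled cRNA was made from 150 ng with a 3′ in vitro transcription kit, and each replicate was hybridised to 1 Affymetrix expression array. The series holds 17 arrays, 6 of control cultures, 5 at 10 nM and 6 at 100 nM. The labels call the replicates biological, so the p-values measure the spread between separately cultured pairs of bulbs. The RNA integrity number was 10 for the 15 arrays whose labels give one. The labels give none for 10 nM replicates 1 and 2, which are both used in the comparisons below.

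Per the submitters' design notes, 10 nM replicates 4 and 5 were judged outliers from a principal component analysis and a low yield of labelled cRNA, which the labels give as 25.66 and 33.68 µg, and were left out of the statistics. The comparisons here used the same 15 arrays, leaving 6 control, 3 at 10 nM and 6 at 100 nM. Values of the 2 set-aside arrays are given only as values and in 1 alternative.

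The deposited values are log2 expression values per probe set, made by the authors with GCRMA, which corrects background using probe sequence, normalizes the arrays to each other and summarises probes into probe sets. The labels do not state the base of the logarithm. Base 2 is the scale GCRMA writes, and the values, which run from 2.11 to 16.9, have the range of that scale. The GCRMA version is not given in the sources used here, nor is it stated whether the set-aside arrays were normalized with the others. Between 29.6% and 32.2% of the probe sets of each array lay at a shared floor near 2.11, so a change that starts at that floor is compressed and its fold is a lower bound. Array medians lay between 4.29 and 4.47. The number of arrays, and for low signals the background, limits the precision.

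Of 31099 probe sets in the file, 57 are the manufacturer's controls. The probe set table used here listed 21268 probe sets, of which 20832 carried 1 gene, 436 carried several genes and were given no gene, and 9780 of the file's probe sets were not listed. Gene identifiers of 20764 single-gene probe sets matched the gene table of the rat assembly GRCr8 and 68 did not. Probe sets were tested if their value was above 2.285, the 40th percentile of all values of the 15 arrays, in at least 3 arrays, the size of the smallest group. This left 18938 probe sets, 14545 of them with 1 gene, covering 10665 genes. Where a gene had several probe sets, the one with the highest mean over the 15 arrays stood for it, and the others were checked for disagreement.

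All 3 groups were fitted together with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, so that they shared 1 estimate of the spread. The 3 comparisons were 100 nM against control, 10 nM against control and 100 nM against 10 nM. Tests were 2-sided and p-values were adjusted by the Benjamini-Hochberg method over the 18938 probe sets of each comparison, with a threshold of 0.05. A gene or probe set is said to have risen, fallen or changed only where it passed this threshold. Errors of log2 changes are limma's moderated standard errors, and errors of group means are SDs. In 1 simulated data set with the same layout, true changes of 0.5, 1 and 2 log2 units were recovered in 49.3%, 82.1% and 97.0% of 67, 67 and 66 probe sets for 100 nM against control, and in 29.9%, 70.1% and 95.5% for 10 nM against control. There, 11 of 163 and 9 of 139 calls were false. These shares moved with the random draw and are rough. Only those probe sets were changed in the simulation, far fewer than were called in the real comparisons with control. The Benjamini-Hochberg cut depends on the share of changed probe sets, so the recovery does not carry over directly.

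Agreement between the doses was measured across probe sets as Pearson's r and the covariance of the log2 changes, with 100 simulations of unchanged groups against the same controls and with the 6 controls split into separate sets of 3 (20 ordered splits). Genes are not independent replicates, so no p-value is attached to it. The simulations drew each probe set independently of the others.

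The text also tests 29 gene lists (867 genes, 608 with a tested probe set), covering ligand and receptor pathways, matrix, cell cycle, stress and metabolism, and markers of cell types that a gubernaculum dissection can hold. The 28 lists with at least 3 measured members were tested with camera, which compares a list's genes with all other genes, using a preset correlation of 0.01 between genes and again with a correlation estimated from the arrays. Camera p-values were adjusted over the 28 lists. No list passed 0.05 with the estimated correlation in the comparisons with control, and each such p is given beside its call. For each list, members past the threshold are counted both over all probe sets and adjusted over the list alone.

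Named genes followed a rule. For 100 nM against control it took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, and for each of the other comparisons the 5 largest of each direction. It added up to 3 members per list with the smallest p among those past the threshold at 100 nM. The rule also took 2 receptor genes in any case, which had no probe set under their name in the annotation used and are not analysed here. The rule, lists, comparisons, tests, filter and most alternatives were fixed before the data were examined.

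The alternatives were no filter and a filter at the 60th percentile, quantile normalization of the arrays again, centring each array on its median, eBayes with an intensity trend and robust estimation, a fit of only the 2 groups compared, all 17 arrays, replicate number as a block, log2 cRNA yield as a covariate, array weights, an added threshold of 1 on the absolute log2 change, and leaving out each array in turn. The lists were also tested with the mean over all probe sets of a gene. Replicate numbers are shared between the groups, but the labels do not say that they pair the cultures.

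Several steps were chosen after the data were seen. Principal components within groups separated replicate numbers 1, 2 and 6 from 3, 4 and 5, so that division was added as a term and as separate fits; the labels give no batch. The mean of the erythroid markers was added as a covariate. Lists of fetal hepatocyte, granulocyte and granulosa cell genes, an exact permutation test of each list's mean between control and 100 nM arrays, the erythroid mean in arrays with little hepatocyte signal, gene lengths, the behaviour of a gene's other probe sets, and the simulated share of equal signs among probe sets with the largest t were also added. The list test of 100 nM against 10 nM was not planned either. A set of 13 genes named in the closing observations was picked from its values.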

Results

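Gene expression was measured in cultured fetal rat gubernacula to ask which transcripts respond to Insl3, the testicular hormone that drives gubernaculum growth during testis descent, and whether 10 and 100 nM differ. The comparisons rest on 15 arrays of separately cultured pairs of bulbs, 6 of control cultures, 3 at 10 nM and 6 at 100 nM. Signals are GCRMA log2 values, and the number of arrays limits their precision. The kept arrays correlated with each other at r of 0.978 to 0.996 across tested probe sets. On the first principal component of the kept arrays, which held 29.3% of the variance, all 6 controls lay on the opposite side from all 9 kept Insl3 arrays. Within the groups, the main component (27.3% of the remaining variance) separated replicates 1, 2 and 6 from replicates 3, 4 and 5 of the control and 100 nM cultures. The labels name no batch for this division, so counts within each set of replicates are given beside the pooled counts. Comparisons with 10 nM in replicates 3, 4 and 5 are left out, since that set holds a single 10 nM array. The median SD of a probe set between replicates was 0.20 in controls, 0.11 at 10 nM and 0.18 at 100 nM.

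After 24 h at 100 nM Insl3, an enzyme gene and genes of secreted signals were among those with the largest rises. Gda, which encodes the purine-degrading enzyme guanine deaminase, rose 65.3-fold, from 2.75 ± 0.14 to 8.78 ± 0.44 log2 units (SD, n = 6 and 6; adjusted p = 1.26e-10, limma). Pnoc, the precursor of the neuropeptide nociceptin, rose 53.8-fold from 7.70 ± 1.21 to 13.45 ± 0.27, among the strongest signals on the arrays. Nppc, the precursor of C-type natriuretic peptide, rose 25.4-fold, and Inhbb, which encodes the activin and inhibin beta B subunit, rose 17.5-fold. Transcripts of blood cells fell over the same comparison, among them Slc4a1, the red cell anion exchanger, which was 8.85-fold lower.

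The other 8 of the 12 largest rises were as follows. S100g, a vitamin D responsive calcium-binding protein, rose by 5.76 ± 0.58 log2 units (SE; adjusted p = 3.57e-05), with 4 of the 6 controls below the filter value, so its 54.4-fold change is compressed. Wnt2, a secreted Wnt ligand, was below the filter value in all 6 controls and rose at least 16.5-fold; its second probe set also rose, by 3.20 log2 units. Asphd2 was at the background floor in all 6 controls and rose at least 8.78-fold, although its values at 100 nM ranged from 3.77 to 7.20. The collagen VIII chain gene Col8a1 rose 19.3-fold, a compressed value because 2 of the 6 controls were below the filter value, and the oestrogen-responsive gene Greb1 rose from 2.92 to 6.92. Pde10a, a cyclic nucleotide phosphodiesterase, rose 12.4-fold, Chrdl2, a chordin-like BMP antagonist, 11.8-fold, and Sphkap, an anchor protein of protein kinase A, 9.49-fold. For these 12 genes every array at 100 nM lay above every control array, and the calls held in all 15 fits that left out 1 array.

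**Figure D1:**
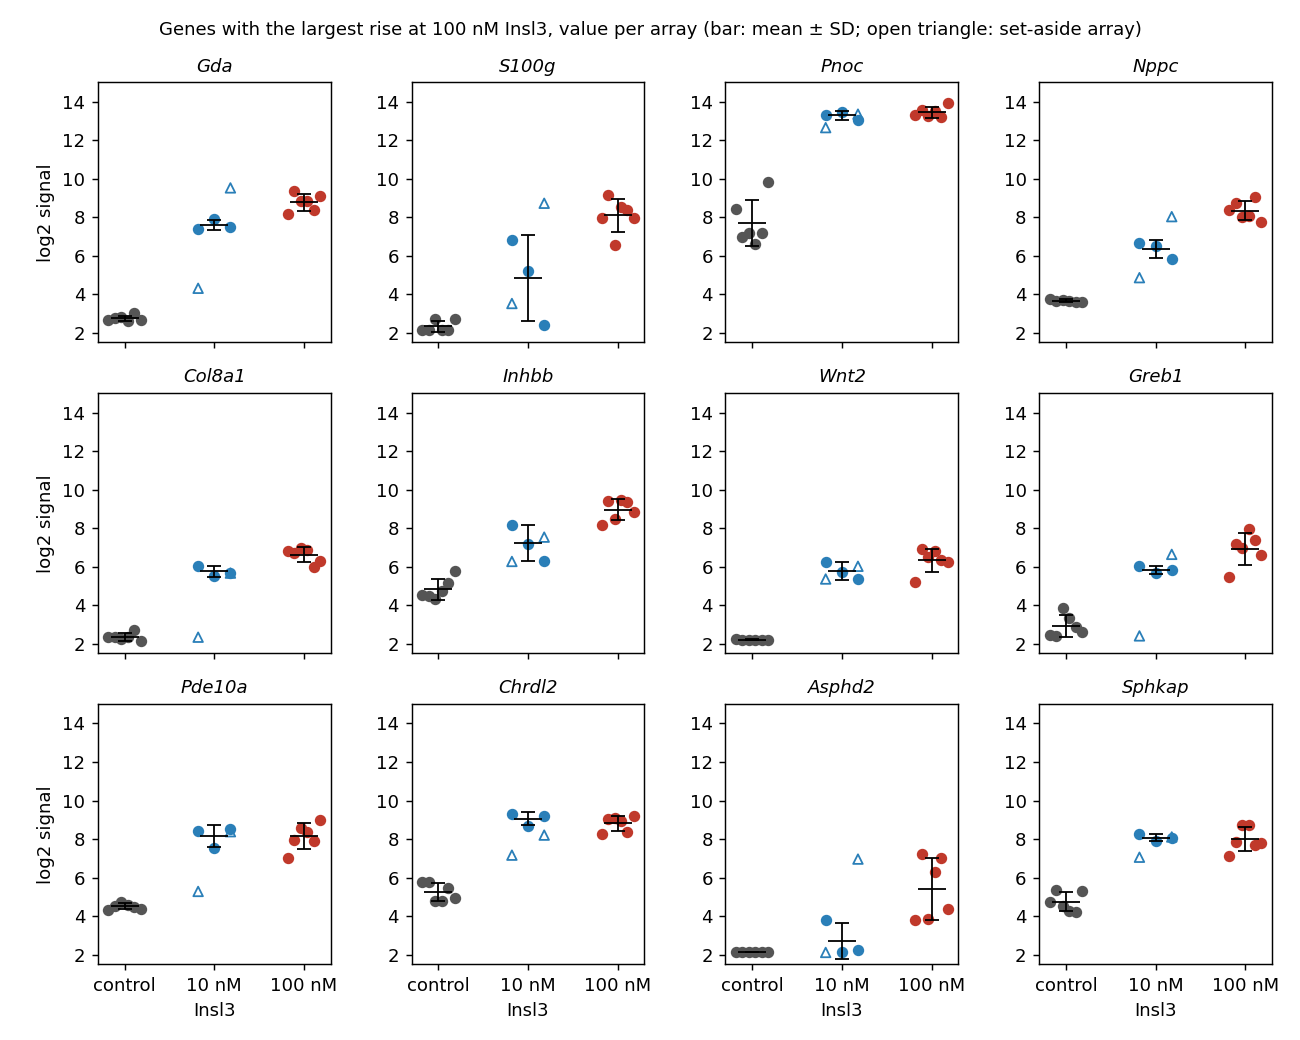
GCRMA log2 signal per array (y axis) of the 12 genes with the largest rise at 100 nM, in control, 10 nM and 100 nM cultures (x axis); bars are mean ± SD of the kept arrays (n = 6, 3 and 6) and open triangles are the 2 set-aside 10 nM arrays. Gda averaged 2.75 in controls, 7.59 at 10 nM and 8.78 at 100 nM, while Pnoc averaged 13.28 at 10 nM and 13.45 at 100 nM.

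The list of genes known to respond to cyclic AMP was called higher at 100 nM. Of 20 measured members 9 rose, none fell and 11 did not pass the test, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.05e-06; adjusted p = 0.189 with an estimated correlation). Besides Pde10a they included the orphan nuclear receptor gene Nr4a1, which rose 4.59-fold (2.20 ± 0.14 log2 units), and Crem, a cyclic AMP response modulator, which rose 2.79-fold and whose other 4 probe sets rose as well. In the Wnt pathway 12 of 31 members rose and 2 fell, against 14 and 3 adjusted over the list alone (adjusted p = 7.19e-05; adjusted p = 0.189 with an estimated correlation). Wnt4, already high in controls at 11.25, rose 3.60-fold, and the receptor gene Fzd1 rose 1.82-fold.

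In other signalling lists single genes changed strongly, and camera called none of these lists. In the BMP and TGF-beta list 8 of 38 members rose and 1 fell (10 and 1 adjusted over the list alone), with a median of -0.01, a mean of 0.28 and a camera adjusted p of 0.504. The rises were led by Inhbb and Chrdl2, and the activin-binding protein gene Fst rose 1.81-fold. In the Hedgehog and FGF list 4 of 18 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.470). Its receptors moved apart, since Fgfr2 rose 3.20-fold and Fgfr1 1.55-fold while Fgfr4 was 1.34-fold lower. In the Notch list 2 of 15 rose and none fell, the same counts as adjusted over the list alone (adjusted p = 0.568, directed down with a median of -0.04 and a mean of 0.03). These were the transcription factor gene Hey2 (0.75 log2 units) and the glycosyltransferase gene Rfng (0.42), whose calls were lost in 6 and 7 of the 15 fits without 1 array (adjusted p up to 0.0757 and 0.0737); a second Rfng probe set changed by 0.11 and was not called. In the retinoid list Crabp2, a retinoic acid binding protein gene, rose 1.43-fold as the only call of 13 (2 higher adjusted over the list alone; adjusted p = 0.250). In the steroid list 2 of 12 fell and none rose (3 lower adjusted over the list alone), namely the kinase gene Sgk1 (-0.61) and the nuclear receptor coactivator gene Ncoa4 (-0.42). That list's median of 0.05 and mean of 0.09 were positive while camera pointed down (adjusted p = 0.504). The 2 measured members of the Insl3 and relaxin list, too few for camera, were not called over all genes or over the list alone, with a median change of -0.36.

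Some genes of neurotrophic signalling rose, and several axon guidance genes fell. Gfra3, the artemin co-receptor, rose 3.51-fold (1.81 ± 0.14 log2 units, adjusted p = 1.66e-06), the neurotrophin receptor gene Ngfr rose 2.60-fold and the neurotrophin gene Bdnf rose 2.42-fold. In that list of 19, 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.614). Its mean was 0.14, with camera pointing up. Among 41 axon guidance genes 4 rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.0818). The semaphorin gene Sema3d was 3.12-fold lower and its receptor family member Nrp2 2.43-fold lower, while Sema3f rose 1.68-fold. Of 13 neuron markers only Uchl1 rose (0.72), also the only call adjusted over the list alone (adjusted p = 0.890). Of 7 Schwann cell markers Ngfr and Pmp22 (0.37) rose and Mbp fell, with the same 2 and 1 adjusted over the list alone (adjusted p = 0.504). A second Pmp22 probe set changed by 0.40 and was not called, and the low Mbp signal fell by 0.28, a call lost in 13 of 15 fits without 1 array (adjusted p up to 0.102).

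Few muscle genes changed. Of 40 skeletal muscle genes 2 fell and none rose, the same counts as adjusted over the list alone, with a mean of -0.13 (camera adjusted p = 0.0144; adjusted p = 0.692 with an estimated correlation and 0.348 without 100 nM replicate 6). They were the muscle receptor kinase gene Musk (-0.49, from a low 3.24) and the myogenic factor gene Myod1 (-0.32, lost without 100 nM replicate 2 or 6, adjusted p up to 0.0539). Of 17 smooth muscle markers only Mylk, the myosin light chain kinase gene, fell (-0.60; a second, weak probe set changed by -0.26 and was not called). Adjusted over the list alone 3 were higher and 2 lower, and camera pointed down (adjusted p = 0.867) while the mean was 0.22 and the median 0.002.

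Matrix genes moved in both directions. In the list of fibrillar collagens and matrix proteins 5 of 36 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.382). Eln, which encodes elastin, rose 1.55-fold and Col6a2 1.63-fold, with a weak second Col6a2 probe set at 0.16 and not called, while Col14a1 was 1.84-fold lower. Of 23 hyaluronan and proteoglycan genes 3 rose and 2 fell, the same counts as adjusted over the list alone. Sdc2 and Sdc1, which encode syndecans, rose by 0.58 and 0.53 log2 units, and Lum, which encodes lumican, was 1.27-fold lower. Both the median and the mean of that list were 0.06 although camera pointed down (adjusted p = 0.867). Of 30 matrix proteases and inhibitors 6 rose and 1 fell (9 and 3 adjusted over the list alone; adjusted p = 0.179). Plat, the tissue plasminogen activator gene, rose 1.41-fold and the serpin gene Serpinf1 1.42-fold, while the aggrecan-degrading protease gene Adamts5 was 1.78-fold lower.

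The lists of lipid synthesis and of hypoxia were called higher at 100 nM. Of 21 cholesterol and lipid synthesis genes 8 rose and none fell, and 15 were higher adjusted over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.322 with an estimated correlation). Srebf1, a sterol regulatory transcription factor gene, rose 1.76-fold, Insig1 1.53-fold and Msmo1 1.41-fold. Of 26 hypoxia and glycolysis genes 8 rose and none fell, with 9 higher adjusted over the list alone (adjusted p = 0.00622; adjusted p = 0.189 with an estimated correlation). The oxygen-sensing prolyl hydroxylase gene Egln3 rose 3.10-fold, Adm, which encodes adrenomedullin, 2.30-fold, and the collagen prolyl hydroxylase gene P4ha1 1.46-fold. Of 27 stress and unfolded protein response genes 6 rose and 2 fell (10 and 4 adjusted over the list alone; adjusted p = 0.221), with small rises of the chaperone genes Pdia4 (0.50), Pdia6 (0.36) and Hsp90b1 (0.34). The cell cycle list shifted slightly down, with a mean of -0.12 over 43 genes (adjusted p = 7.19e-05; adjusted p = 0.322 with an estimated correlation). Only Ccna2 (-0.47) and Bub1 (-0.29) fell, also the 2 calls adjusted over the list alone, and the Bub1 call was lost in 5 of 15 fits without 1 array (adjusted p up to 0.0650).

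Among transcription factors of the limb and urogenital region, 3 of 26 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.867). Twist2, a mesenchymal factor gene, rose 7.11-fold (2.83 ± 0.31 log2 units), Osr2 rose 2.05-fold and Hoxc9 fell by 0.27. Of 11 adipocyte markers Cfd, which encodes adipsin, rose 4.04-fold and Cebpb 1.82-fold, while 2 fell, among them the fatty acid transporter gene Cd36 (-0.81). Adjusted over the list alone 3 were higher and 3 lower (adjusted p = 0.504). Of 16 endothelial markers 3 rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.641). The tight junction gene Cldn5 rose 7.13-fold from a high 9.51, and the VEGF receptor gene Kdr rose 1.92-fold and Ramp2 1.53-fold. Of 5 chondrocyte and osteoblast markers only Sox6 fell (-0.55; adjusted p = 0.110), also the 1 call adjusted over the list alone, and a second Sox6 probe set changed by -0.56 without being called. None of 12 mesothelium and epithelium markers changed, over all genes or adjusted over the list alone (camera adjusted p = 0.726, pointing down with a median of -0.004 and a mean of 0.05).

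Erythroid and granulocyte genes were among the largest falls. Of 11 erythroid markers 5 fell and none rose, with 8 lower adjusted over the list alone and a mean change of -2.01 (camera adjusted p = 1.99e-06; adjusted p = 0.322 with an estimated correlation). Besides Slc4a1 (-3.15 ± 0.63 log2 units, adjusted p = 0.00625), the erythroid transcription factor gene Klf1 was 8.27-fold lower and Epb42, a red cell membrane protein gene, 5.47-fold lower. The mean of the 11 erythroid markers was 9.48 ± 1.07 in controls and 7.47 ± 0.99 at 100 nM (SD, n = 6 and 6). Nfe2 (-2.95), Car2 (-2.69), Dyrk3 (-3.31), Hemgn (-2.85) and Urah (-3.25) also fell, as did the leukocyte surface gene Cd52 (-2.81). Granulocyte genes fell too, namely Prg2 (-3.33), S100a9 (-3.24) and S100a8 (-2.77). The largest fall was that of the myosin gene Myo5c, 12.4-fold lower (-3.64 ± 0.73). The SDs of these genes within groups were large, as with 1.52 and 2.21 for S100a9 in control and 100 nM arrays. Without 1 array the calls of Hemgn, S100a9, S100a8 and Urah were lost in 11, 11, 9 and 4 of 15 fits, with adjusted p up to 0.0869, 0.0952, 0.0876 and 0.0539.

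The list of leukocyte and macrophage markers was also called lower at 100 nM. Of 18 members 4 fell and none rose, with 5 lower adjusted over the list alone and a mean of -0.36 (adjusted p = 8.05e-06; adjusted p = 0.390 with an estimated correlation). Lcp1 (-0.54), Ptprc (-0.65) and the macrophage mannose receptor gene Mrc1 (-0.63) were among them. A weak second Ptprc probe set changed by -0.26 and was not called, and the Mrc1 call was lost in 5 of 15 fits without 1 array (adjusted p up to 0.0538). The interferon and inflammatory list had a mean of -0.31 with no member called over all genes or over the list alone (adjusted p = 0.0248; adjusted p = 0.481 with an estimated correlation). Its call was lost without control replicate 5 (0.0543), 100 nM replicate 2 (0.0512) or 100 nM replicate 6 (0.0513). With the erythroid mean as a covariate, added after the data were seen, 58 of the 103 calls of named genes in the 3 comparisons remained. That mean itself differed between control and 100 nM, so the covariate can take up part of a dose effect.

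**Figure D2:**
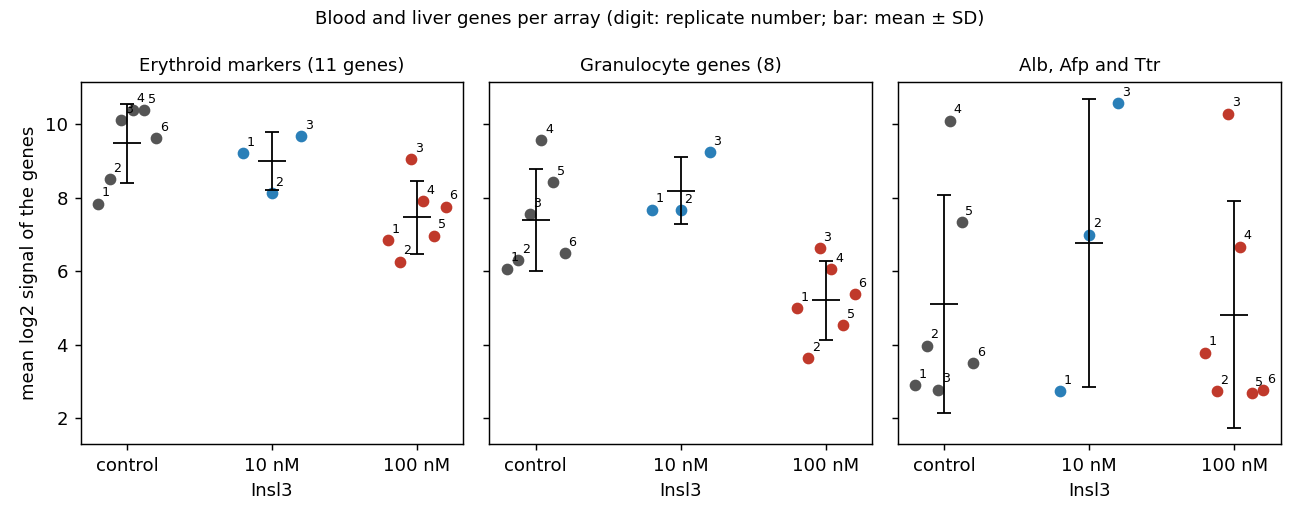
Mean log2 signal per array (y axis) of 11 erythroid markers, 8 granulocyte genes and the hepatocyte genes Alb, Afp and Ttr in control, 10 nM and 100 nM cultures (x axis); digits are replicate numbers and bars are mean ± SD (n = 6, 3 and 6). The erythroid mean was 9.48 in controls, 9.01 at 10 nM and 7.47 at 100 nM, and single arrays of each group stood out in the hepatocyte genes.

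In total 2065 of 18938 probe sets changed at 100 nM (limma), 1233 higher and 832 lower, and 363 of them changed at least 2-fold, 258 higher and 105 lower. By the probe set standing for each gene, 869 genes rose and 424 fell. The count was 1691 among replicates 3, 4 and 5 alone but 200 among replicates 1, 2 and 6 alone, and 2456 with that division as a term in the fit. It was 1008 with the set-aside arrays included and 751 with the erythroid mean as a covariate. That mean itself differed between these groups, so the covariate can take up part of a dose effect.

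**Figure D3:**
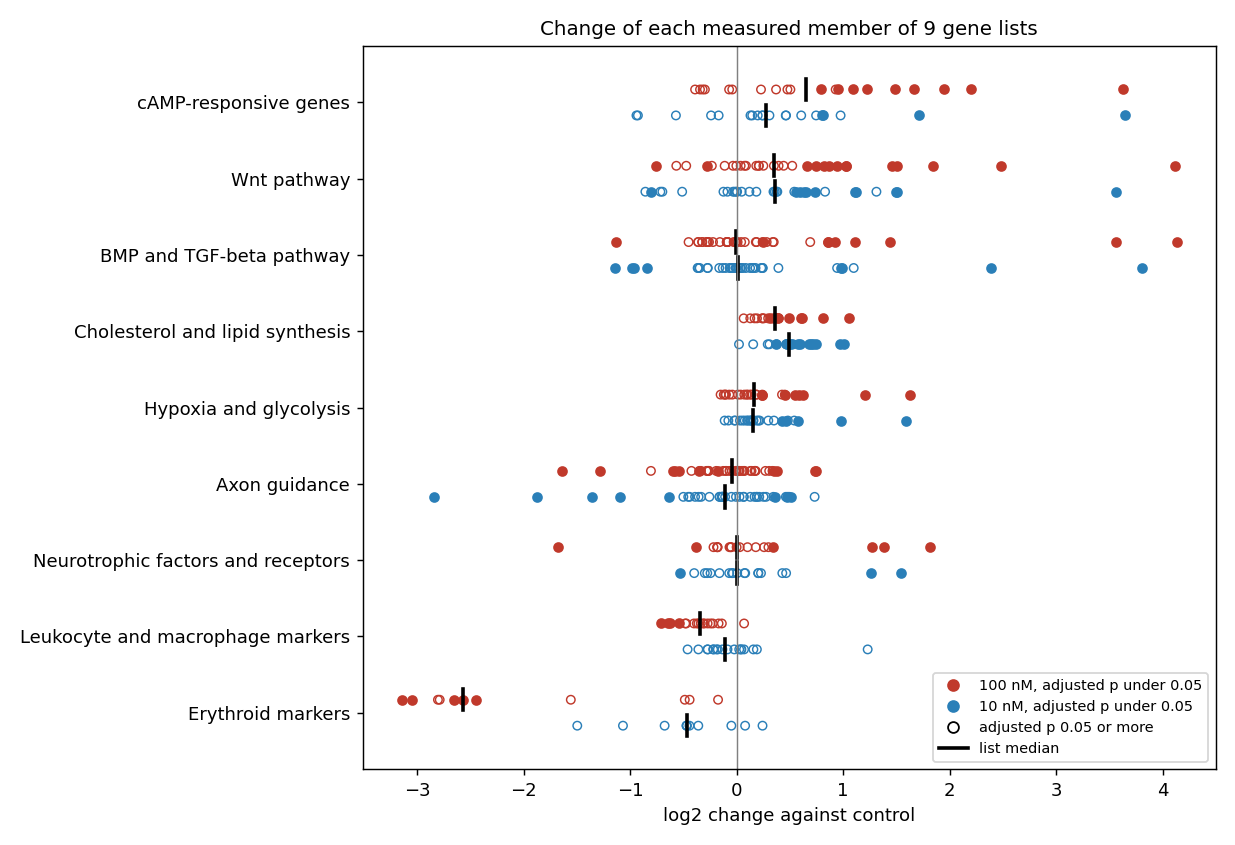
Log2 change against control (x axis) of each measured member of 9 gene lists, at 100 nM (red) and 10 nM (blue); filled points passed an adjusted p of 0.05 and black bars are list medians. The erythroid median was -2.57 at 100 nM and -0.47 at 10 nM, and the cholesterol median was 0.36 and 0.49.

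At 10 nM the same leading genes were already raised. Pnoc rose 48.1-fold (5.59 ± 0.53 log2 units, SE, n = 3 and 6; adjusted p = 4.39e-05, limma), Gda 28.6-fold, Chrdl2 14.0-fold and Pde10a 12.5-fold. Wnt2 rose at least 11.3-fold. Of the 12 genes with the largest rise at 100 nM only Asphd2 was not called at 10 nM. The largest falls were of other genes than at 100 nM, led by Sema3d, which fell by 2.84 ± 0.31. Ppp1r9a, a neuronal actin-binding protein gene (-2.73), Tmem26 (-2.60), Pi4k2a, a phosphatidylinositol kinase gene (-2.57), and Bod1l1 (-2.52) followed. Sema3d and Bod1l1 also fell at 100 nM (-1.64 and -1.05), and the 100 nM against 10 nM test did not separate the doses for them (adjusted p = 0.0705 and 0.0526). None of the 12 genes with the largest fall at 100 nM was called at 10 nM, and none of them passed the test of 100 nM against 10 nM.

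Of the 28 tested lists, 2 passed at 10 nM, a number that depended on single arrays. It was 8 without control replicate 3, 7 without control replicate 5 or 10 nM replicate 1, 6 without 100 nM replicate 1, 5 without control replicate 1 or 10 nM replicate 2, 4 without 10 nM replicate 3 and 1 without control replicate 2, and 7 after quantile normalization again or with all 17 arrays. In cholesterol and lipid synthesis 12 of 21 genes rose and none fell, with 17 higher adjusted over the list alone (camera adjusted p = 1.30e-08; adjusted p = 0.454 with an estimated correlation). Srebf1 rose 1.96-fold, Insig1 1.60-fold and Msmo1 1.51-fold. In hypoxia and glycolysis 5 of 26 rose and none fell (7 higher adjusted over the list alone), including Egln3 at 3.01-fold. Its adjusted p was 0.0369, 0.454 with an estimated correlation and 0.0539 without control replicate 2.

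No signalling list passed at 10 nM with all 15 arrays. In the Wnt list 10 of 31 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0582), with Wnt4 at 2.81-fold and Fzd1 at 1.47-fold. In the cyclic AMP list 4 of 20 rose, the same count as adjusted over the list alone (adjusted p = 0.0914), among them Crem at 1.74-fold. In the BMP and TGF-beta list 4 rose and 4 fell, also adjusted over the list alone, with Inhbb up 5.24-fold; its mean was 0.16 and its median 0.01 while camera pointed down (adjusted p = 0.651). In the Hedgehog and FGF list 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.926), with Fgfr2 up 2.59-fold and Fgfr4 at -0.46. Gfra3 rose 2.92-fold and Ngfr 2.39-fold. In the neurotrophic list 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.926), and camera pointed down against a mean of 0.13. In axon guidance 3 rose and 5 fell (4 and 6 adjusted over the list alone; adjusted p = 0.0616), with Nrp2 at -1.36. Neither the Notch, the retinoid nor the steroid list had a called member (adjusted p = 0.753, 0.651 and 0.816), over all genes or over the list alone, and nor had the 2 relaxin family members. Camera pointed down for the Notch list against a mean of 0.02.

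No matrix list passed at 10 nM with all 15 arrays. Collagens and matrix proteins had 6 higher and 1 lower of 36 (9 and 1 adjusted over the list alone; adjusted p = 0.0591), with Eln up 1.64-fold. Matrix proteases had 7 higher and 3 lower of 30 (10 and 3 adjusted over the list alone; adjusted p = 0.0834), with Plat up 1.40-fold and Adamts5 at -0.55. Hyaluronan and proteoglycans had 3 higher and 1 lower of 23 (3 and 3 adjusted over the list alone; adjusted p = 0.753). The stress list had 2 rising members of 27 (1 adjusted over the list alone; adjusted p = 0.259), Pdia6 among them at 0.25. In the cell cycle list 2 fell, also adjusted over the list alone (adjusted p = 0.116), and in the limb and urogenital factor list 3 fell, also adjusted over the list alone (adjusted p = 0.0582), including Hoxc9 at -0.57.

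No list of cell type markers passed at 10 nM with all 15 arrays. Endothelial Cldn5 rose 3.04-fold, Kdr 1.72-fold and Ramp2 1.39-fold, the 3 calls of that list (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.892). Adipocyte Cfd (1.49) and Cebpb (0.67) rose, the same 2 as adjusted over the list alone (adjusted p = 0.674). Skeletal muscle markers had 3 lower of 40, also adjusted over the list alone (adjusted p = 0.0582), with Musk at -0.51. Smooth muscle markers had 1 higher and 2 lower of 17, also adjusted over the list alone (adjusted p = 0.926), with Mylk at -0.35. Neuron markers had 1 rise, also adjusted over the list alone (adjusted p = 0.503, pointing down against a mean of 0.01), and Schwann cell markers had 2 rises (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.563). Sox6 at -1.27 was the only chondrocyte call, also adjusted over the list alone (adjusted p = 0.560, pointing down against a mean of 0.27), and its second probe set at -0.36 was not called. No erythroid, leukocyte or mesothelium marker was called, over all genes or adjusted over the list alone (adjusted p = 0.0914, 0.0914 and 0.926), and the mesothelium mean of 0.29 ran against camera's direction. In the interferon list 1 member fell over all genes and none adjusted over the list alone (adjusted p = 0.651, pointing down against a mean of 0.16).

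At 10 nM 2004 probe sets changed (limma), 925 higher and 1079 lower, and 714 changed at least 2-fold, 184 higher and 530 lower. By the probe set standing for each gene, 591 genes rose and 334 fell. The falls were often not shared by other probe sets of the same gene that lay well above the filter value in controls. On average 56.6% of these had the same sign as a probe set called lower at 10 nM. The share was 70.7% for those called higher at 10 nM and 86.0% for those called lower at 100 nM. Which direction held more calls varied. More were higher after median centring (1250 higher and 980 lower), with array weights (2300 and 1908) and with the yield covariate (932 and 918). Among replicates 1, 2 and 6 there were 125 higher and 434 lower. Replicates 3, 4 and 5 hold a single 10 nM array, so a count from them alone is left out. The count of probe sets was 559 among replicates 1, 2 and 6, and 2190 with that division as a term. It was 1256 without 10 nM replicate 1, 1020 without 10 nM replicate 3 and 4208 with array weights.

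Measured directly, the doses differed in 83 genes by the probe set standing for each, 67 of them higher and 16 lower at 100 nM. Nppc was higher at 100 nM by 1.99 ± 0.25 log2 units (SE, n = 6 and 3; adjusted p = 0.00518, limma), and Nr4a1 by 1.73 (adjusted p = 0.00110). S100g was higher by 3.27, Gda by 1.19 and Twist2 by 1.76 (adjusted p = 0.0410, 0.0229 and 0.0400), and Fst by 0.61 (adjusted p = 0.0182). The second probe sets of Gda and Fst differed by 0.23 and 0.45 and were not called (adjusted p = 0.687 and 0.214). Pi4k2a (2.23), Rab27b (2.08) and Mgll (1.85) were also higher at 100 nM, each with a fall at 10 nM against control and no call at 100 nM against control. The other probe sets of Rab27b (1 more) and Mgll (2 more) did not follow, with differences of 0.23, 0.13 and 0.15. Lower at 100 nM than at 10 nM were Dedd2 (-3.16), Creg1 (-2.78), Epb42 (-2.69), the blood lineage transcription factor gene Lyl1 (-2.59) and Sgk1 (-0.87), all of which fell at 100 nM against control. The second Creg1 probe set gave -2.04 with an adjusted p of 0.0534.

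A test of the lists in this comparison, which was not planned, called 7 of 28. The cyclic AMP list was higher at 100 nM, with 1 member higher of 20 and 2 adjusted over the list alone (camera adjusted p = 1.29e-04; adjusted p = 0.409 with an estimated correlation). The limb and urogenital factor list was higher (1 of 26, 4 adjusted over the list alone; adjusted p = 1.91e-04; adjusted p = 0.409 with an estimated correlation). The erythroid list was lower (1 of 11, 3 adjusted over the list alone; adjusted p = 1.91e-04; adjusted p = 0.409 with an estimated correlation). The leukocyte list was also lower, with no member called over all genes and 1 adjusted over the list alone (adjusted p = 0.00177; adjusted p = 0.510 with an estimated correlation). The Wnt list (1 higher, also adjusted over the list alone; adjusted p = 0.0129) and the BMP and TGF-beta list (1 higher, 3 adjusted over the list alone; adjusted p = 0.0215) were higher, and the cell cycle list was lower by its mean of -0.09 with 1 member higher (adjusted p = 0.0135). With an estimated correlation these gave adjusted p = 0.409, 0.409 and 0.501.

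In total 271 probe sets differed between the doses, 234 higher and 37 lower at 100 nM, and 127 differed at least 2-fold. Of the 234, 203 had fallen at 10 nM against control and 24 had risen at 100 nM against control. For probe sets lower at 10 nM, other probe sets of the same gene often did not follow, as given above. The 37 lower ones included 17 that fell at 100 nM and 19 that rose at 10 nM against control. This count rested on single arrays more than the others did. It was 3 without 10 nM replicate 3, where the Nppc call was also lost (adjusted p = 0.0518), 101 and 127 without 10 nM replicates 1 and 2, and 619 without 100 nM replicate 5. It was 149, 149 and 133 without control replicates 3, 4 and 5, and 139, 56, 121 and 98 without 100 nM replicates 1, 2, 3 and 6. None of the 10 genes the naming rule took here kept its call in all 15 of these fits. Within replicates 1, 2 and 6 it was 134, and with that division as a term 531. Replicates 3, 4 and 5 hold a single 10 nM array, so a count between the doses from them alone is left out.

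The changes at the 2 doses ran in the same direction. Across 18938 probe sets the log2 changes correlated at r = 0.688 (jackknife SE 0.0820), against 0.361 to 0.451 in simulations where only the shared controls linked the doses. These simulations drew each probe set independently. Real probe sets vary together, so the simulated ranges of r and of equal signs are too narrow. With separate controls for each dose the mean r was 0.544, ranging from 0.355 to 0.686, and the covariance was 0.104, close to the 0.105 that remained of 0.121 after the simulated 0.0157. Both doses raised 597 probe sets and both lowered 315. No probe set was called in opposite directions. Of the calls at 100 nM, 96.9% had the same sign at 10 nM, against at most 82.9% for as many probe sets with the largest t in the simulations. A further 764 probe sets were called lower only at 10 nM and 517 only at 100 nM, and whether each such probe set differed between doses rests on the direct test of the doses. With the set-aside arrays included r was 0.556.

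**Figure D4:**
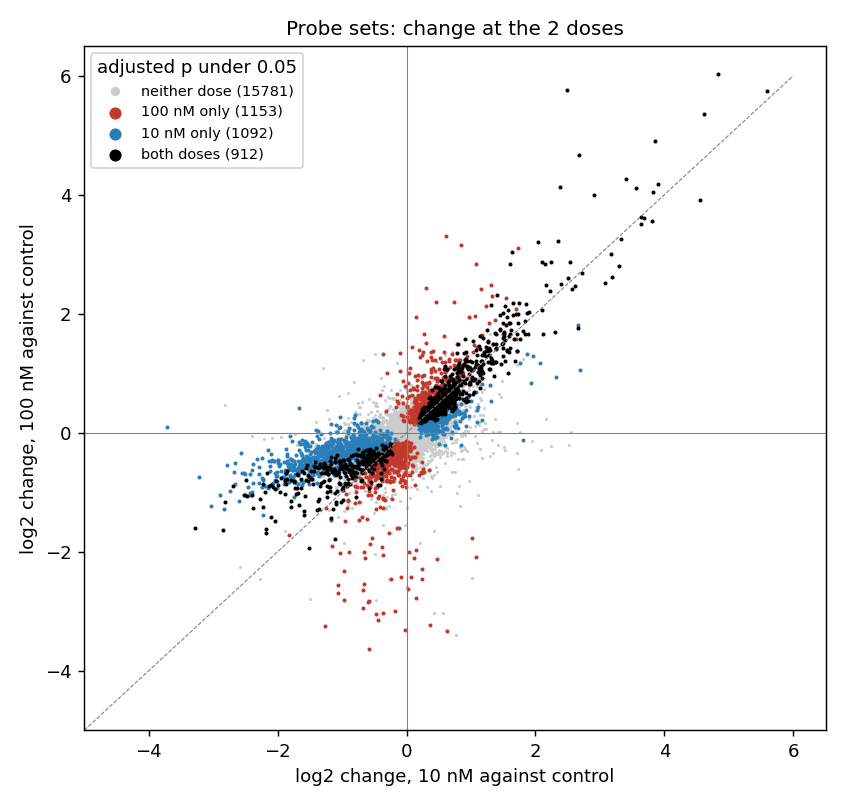
Log2 change at 10 nM (x axis) and at 100 nM (y axis) against control for each tested probe set; black points were called at both doses (912), red at 100 nM only (1153), blue at 10 nM only (1092) and grey at neither (15781), and the dashed line marks equal change. The points called at both doses lie in the quadrants of equal sign (597 higher and 315 lower).

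The 2 set-aside 10 nM arrays, replicates 4 and 5, correlated with the kept arrays at 0.954 to 0.969 and 0.952 to 0.967. Placed on the first principal component of the kept arrays, they lay at 5.41 and -12.2, the second on the side of the controls. Their Gda values were 4.31 and 9.52, against 7.38 to 7.89 in the kept 10 nM arrays, and their erythroid means were 10.4 and 11.5, against 9.01 ± 0.79.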

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

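The tests of the blood cell genes and of the lower calls at 10 nM were chosen after those results were seen, while the tests of other splits of the arrays were fixed beforehand.

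Splits of the same arrays into groups of equal sizes tested whether chance could give the counts. For 100 nM against control, 1 of 100 drawn splits (of 462 possible), the real one, reached its 2065 probe sets, and the highest other gave 52. For 10 nM against control 1 of 84 splits, the real one, reached 2004, and the highest other gave 1023, with control replicates 3, 4 and 5 set against the other 6 arrays. For 100 against 10 nM 1 of 84 splits, the real one, reached 271, and the highest other gave 193, with 100 nM replicates 3, 4 and 5 as the smaller group. By this share chance is argued against for the count at 100 nM against control as fitted. For both comparisons with 10 nM the splits cannot decide, and 84 splits allow no share below 1 of 84. There, 10 nM replicates 4 and 5 had been removed as outliers, while no control or 100 nM array was set aside. The kept 10 nM arrays were also closer together, with a median SD of 0.11 against 0.20 in controls and 0.18 at 100 nM. Splits that mix the groups also widen the spread within groups, which lowers their counts. The 271 was not stable, at 3 with only the 2 groups compared, 22 without a filter and 3 without 10 nM replicate 3. The splits were not repeated in those fits. The highest other splits of both comparisons with 10 nM follow the division between replicates 3, 4 and 5 and replicates 1, 2 and 6. Within replicates 1, 2 and 6 the counts were 559 for 10 nM against control and 134 for 100 against 10 nM.

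Blood cell genes were lower at 100 nM, with the erythroid mean falling from 9.48 to 7.47 (exact permutation p = 0.0130, below the control mean in 6 of 6 arrays, while Hbb, the most abundant member at 16.6 in controls, changed by -0.44 and was not called). A chance spread of blood content between cultures is argued against by the exact permutation p adjusted over 28 lists, 0.0404. The mean of 5 granulocyte genes that the naming rule had not picked (Camp, Epx, Defa5, Np4 and Lcn2, the last also in the interferon list) went from 6.59 to 4.95 (exact permutation p = 0.0325), in line with a lower content of several kinds of blood cells. Whether carry-over of fetal liver was the whole cause cannot be decided, because the test used for it was chosen after the array values were seen. It took the arrays whose mean of Alb, Afp and Ttr lay below the array median (exact permutation p = 0.0286, the smallest possible and not adjusted). In these arrays the erythroid mean was still lower at 100 nM, 9.02 ± 1.03 in controls and 6.96 ± 0.62 at 100 nM (SD, n = 4 and 4). The lowest control lay at 7.84 and the highest 100 nM array at 7.76. Some liver carry-over stays open, because over all arrays these genes averaged 5.10 ± 2.96 and 4.83 ± 3.08 (exact permutation p of the erythroid mean minus theirs 0.236, the first test tried, which decided nothing and was replaced by the test in 4 and 4 arrays after the values were seen) and within groups the erythroid mean followed the hepatocyte list (r = 0.648, rho = 0.582, permutation p = 0.012 and 0.024, 15 arrays; r = 0.667 without the 2 farthest), as do blood left at dissection and an effect of Insl3 on blood content, neither of them tested.

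For the 1079 probe sets lower at 10 nM, a difference in cRNA yield is argued against as the whole cause, since the kept 10 nM arrays (48.6 to 64.2 µg) overlapped the controls (50.3 to 103 µg) and with log2 yield as a covariate 918 probe sets were called lower. Changes of single transcript regions may account for part of them. In 681 cases with other probe sets of the same gene, the others changed by a median of -0.11 against -1.01 for the called ones, a ratio of 0.106, compared with 0.314 for probe sets called higher at 10 nM and 0.535 for those called lower at 100 nM. The 334 genes whose chosen probe set was lower at 10 nM had a median genomic length of 56.9 kb. It was 24.3 kb for all genes tested and at most 33.2 kb in random draws of as many genes. Genomic length is not the length of the RNA, so it cannot decide whether a length bias of RNA or labelling played a part. An effect of the dose itself stays open, and in the set-aside arrays the same probe sets averaged -1.39 and -0.41 against controls.

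Among 194 groups of replicate values checked for a single array far from the others, 15 (7.73%) had one, where chance gives about 1 in 20. In control replicate 6, Ppp1r9a was 3.33 (others 5.31 to 5.79), Crabp2 9.47 (10.1 to 10.4), Nrp2 9.71 (10.3 to 10.6) and Sdc2 10.1 (9.66 to 9.82). In control replicate 1, Bdnf was 5.71 (5.39 to 5.51), Adm 2.86 (3.05 to 3.16) and Asphd2 2.11, at the floor like the others. Control replicate 5 had Col8a1 at 2.71 (2.14 to 2.33) and control replicate 4 had Uchl1 at 8.08 (8.62 to 8.89). In 100 nM replicate 1, Crabp2 was 10.9 (10.4 to 10.6), Serpinf1 14.1 (14.5 to 14.6) and Cd36 7.99 (7.36 to 7.58). In other 100 nM arrays, Klf1 was 5.11 in replicate 3 (2.57 to 3.21), Mbp 2.83 in replicate 6 (others 2.98) and the cRNA yield 77.9 µg in replicate 4 (59.0 to 65.7).

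The doses differed in 271 probe sets by the direct test. In the set-aside 10 nM arrays, used only in the fit of all 17 arrays, 9 and 12 of the 12 genes with the largest rise at 100 nM lay above their highest control value in replicates 4 and 5.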

How the results depend on the processing

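The erythroid covariate and the fits by sets of replicates were chosen after the data were seen. The erythroid mean differed between control and 100 nM, so that covariate can also take up part of a dose effect. The cause of the changes in the counts was not tested. Of 103 calls of named genes none changed direction in any setting, and 101 remained after quantile normalization again, 102 with median centring, 102 with a trend and robust estimation, 102 with array weights, 100 with replicate as a block, 94 with the yield covariate, 86 with only 2 groups in the fit, 84 with all 17 arrays and 103 with the replicate sets as a term. With replicates 1, 2 and 6 alone 35 remained, and with the erythroid covariate 58. Replicates 3, 4 and 5, with a single 10 nM array, are left out of this number. For 100 nM against control (2065) the count was 1008 with all 17 arrays, 200 in replicates 1, 2 and 6, 751 with the erythroid covariate and 363 with an absolute log2 change of at least 1, and 1442 (without control replicate 4) to 2616 (without control replicate 6) with 1 array left out. For 10 nM against control (2004) it was 4208 with array weights, 559 and 754 in the replicate sets and 714 with the size threshold, and 1020 (without 10 nM replicate 3) to 2495 (without control replicate 6) with 1 array left out. The share of higher calls at 10 nM, 46.2%, was 56.1% with median centring, 54.7% with array weights and 50.4% with the yield covariate. It was 22.4% in replicates 1, 2 and 6, 25.8% with the size threshold and 38.5% with replicate as a block. Which direction had more calls thus depends on the processing. For 100 against 10 nM (271) it was 22 without a filter, 3 with only the 2 groups in the fit, 429 with replicate as a block, 85 with the yield covariate, 1199 with array weights, 531 with the replicate sets as a term, 134 and 159 within them, 77 with the erythroid covariate, 127 with the size threshold, and 3 to 619 with 1 array left out. Other alternatives stayed within 1.5 times the counts above, apart from comparisons with 10 nM in replicates 3, 4 and 5, which hold a single 10 nM array. Replicate as a block gave 1781 and 1708 for the comparisons with control. Residuals of arrays with equal replicate numbers correlated at 0.00676 to 0.199 between control and 100 nM, over 0.1 in 4 of 6 pairs, and were the best match in 1 of 6, so the numbers were not taken to pair the cultures, although the division of replicates is shared by both groups. Agreement of the doses (r = 0.688) was 0.556 with all 17 arrays, 0.544 with separate controls, which also leaves only 3 controls per dose, and 0.646 to 0.725 with 1 array left out. With camera's estimated correlation 0 of the 9 lists at 100 nM and 0 of the 2 at 10 nM passed. At 100 nM the other settings gave 9 lists, and 7 to 10 with 1 array left out; at 10 nM 7 lists passed after quantile normalization again, 7 with all 17 arrays, and 1 to 8 with 1 array left out.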

Other observations

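All genes, lists and tests in this part were chosen after the data were seen.

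Several further genes changed at 100 nM with all 6 arrays beyond every control, and each kept its call against control in the fits that left out 1 array. Foxl2, a transcription factor of the ovarian granulosa lineage, rose 8.22-fold (3.04 ± 0.20 log2 units, SE, n = 6 and 6; limma adjusted p = 4.91e-07). The interleukin 33 receptor gene Il1rl1 rose 9.29-fold, the potassium channel subunit gene Kcne4 7.30-fold, and Kitlg, which encodes stem cell factor, 5.61-fold. Receptor genes also rose, among them Adora2a for adenosine (5.32-fold), Itgb3 for matrix proteins (4.54-fold), Adra2a for noradrenaline (4.07-fold) and Agtr2 for angiotensin, which went from 12.63 to 14.05. Cpe, a peptide-processing enzyme gene, rose 3.97-fold. The neuropeptide gene Npy was 4.28-fold lower, the thyrotropin receptor gene Tshr 3.45-fold, the lipase inhibitor gene Angptl4 2.69-fold and the neurokinin receptor gene Tacr3 2.16-fold lower.

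Exact permutation of list means between the 6 control and 6 100 nM arrays treats arrays, not genes, as the units. The smallest p it allows, 0.00217, was reached by the cyclic AMP, Wnt, BMP and TGF-beta, hypoxia, and cholesterol lists, all higher at 100 nM in 6 of 6 arrays against the control mean (0.0121 adjusted over 28 lists). The Hedgehog and FGF list (0.0303) and the smooth muscle list (0.0346) were higher, and the cell cycle list (0.0404) was lower, after the same adjustment, as was the erythroid list (0.0404). The other 19 lists gave 0.0661 to 0.892. The smooth muscle mean rose by 0.22 although camera, which compares a list with all other genes, pointed down for it. The BMP and TGF-beta list had a median change of -0.007 beside its mean of 0.279 (camera adjusted p = 0.504). Its mean does not describe most of its members.

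Of 8 measured granulocyte genes 3 fell at 100 nM and none rose (camera p = 2.00e-04; p = 0.0880 with an estimated correlation), and their mean was 7.40 ± 1.38 in controls, 8.19 ± 0.91 at 10 nM and 5.21 ± 1.07 at 100 nM (SD, n = 6, 3 and 6; exact permutation p = 0.0130 against control). Between the doses the exact permutation p was 0.0119 for the granulocyte mean, the smallest possible, and 0.0357 for the erythroid mean. Within groups the granulocyte mean followed the erythroid mean (r = 0.863, rho = 0.936, permutation p = 4.9e-04 and 3e-05, 15 arrays; r = 0.814 without the 2 farthest). Of 10 measured fetal hepatocyte genes none was called (camera p = 0.845; p = 0.946 with an estimated correlation).

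Inhbb, Foxl2 and Kitlg are known from ovarian granulosa cells, and a candidate explanation is that a wider programme of that cell type rises with Insl3. Of 5 other granulosa cell genes with a tested probe set, Npr2 rose by 0.42, Gatm fell by 0.44, and Inha (-0.09), Inhba (0.69) and Amhr2 (0.01) were not called; 3 of these also belong to the BMP and TGF-beta list. As a set they gave a camera p of 0.860 (0.860 with an estimated correlation), too few and too mixed to decide.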
